A study of Monodelphis domestica with 8 samples.

How the data were processed

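The series holds ChIP-seq libraries from opossum fetal brain at embryonic day 13, with antibodies against H3K4me3, H3K9Ac, H3K9me3 and H3K27me3. Per the labels' protocols, chromatin was digested with micrococcal nuclease, pooled between sisters, and divided equally among the antibodies. There were 8 libraries in all, 2 per mark, and 4 processed peak lists. CASAVA 1.7, Bowtie 1.1.2 and MACS 1.0.1 are named in the submitters' processing notes, without settings. The genome build, the control library, the peak threshold and the way in which the 2 libraries of a mark were combined are not given in the sources used here. Per the labels, both libraries of a mark name the same list, so each list was treated as the authors' pooled result for its mark, with no replicate values, and no test compares samples.

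The deposited lists give the chromosome, start, end, name and score of each peak. The score is the authors' value per peak as deposited and no header says how it was computed. The lowest score is 50 in every list to the nearest whole number, and 110 H3K4me3 and 132 H3K27me3 peaks hold exactly 3100, with 31 and 7 above it. Scores were used only within a list. Peaks of a list did not overlap one another, and 1 H3K9Ac peak and 1 H3K9me3 peak start at a negative position. Starts are printed counting from 1. A gene table of another assembly was at hand and was not used for positions, because 708 peaks on chromosome 8 lie beyond its last gene there. Planned comparisons of promoters, gene lists, CpG content and bases other than N need an annotation or sequence in the coordinates of the lists and were not run.

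Autosomes 1 to 8 were compared with X, and unplaced sequence was left out of the main comparisons. The length of a chromosome was taken as the distance from the first to the last peak of any mark, which gave 76.3 Mb for X. Density is peaks per Mb and cover is the percentage of that length under peaks. X was placed among 10000 random autosomal windows of its own length (two-sided, called the window permutation test because it permutes the position of the window), and 95% intervals of ratios came from 10000 resamples of 1 Mb bins. The random windows overlap one another and are not independent, and an alternative used 40 non-overlapping windows. Co-occupancy needed at least 1 bp in common and was compared with 1000 circular shifts of the second list within each chromosome, for 6 pairs, taking the list with fewer peaks in all as the first. Shares on X and on the autosomes were compared with Fisher's exact test for 12 ordered pairs, with exact conditional 95% intervals. Their error was also taken from 2000 resamples of 1 Mb bins, since peaks are clustered. Medians of score and width were compared by permuting the chromosome class 100000 times. P values were adjusted by the Benjamini-Hochberg method over the 4 marks, 6 pairs, 12 ordered pairs or 8 score and width tests. Domains are peaks of a mark less than 5 kb apart. The threshold was 0.05. Intervals of shares cover counting of peaks only, and depth is unknown because the lists hold no read counts.

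The named regions were fixed before the data were examined as the 5 highest-scoring peaks per mark on X and on the autosomes and the 5 longest joined domains, of which those that carry a comparison are printed. The alternatives fixed then were the top-scoring 50% of peaks, other choices of autosomes, joined peaks, non-overlapping windows, the rank of X among the 9 chromosomes, stricter and looser overlap, and 1 value per 1 Mb bin. Lengths counted from position 0, the removal of peaks shared by all 4 marks, and classes of score were added after the data were seen, as were the division of H3K4me3 peaks by other marks and of H3K9me3 peaks by H3K27me3, the distance profile, the bins and gaps of X, and the correlation along X. The random placement of H3K27me3 peaks, 200 draws within each chromosome in which peaks can overlap, was also added then. The bins and gaps named were chosen after their values were seen.

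The procedures were tested on simulated data with planted values, some chosen near those observed. Simulated peaks were placed at random without clustering, and simulated scores and overlaps were drawn independently. The counts of lists that passed therefore do not give error rates for clustered peaks like those of the deposited lists. A planted X to autosome density ratio of 50 was recovered as 50.01 on average over 20 simulated lists, one of 4 as 4.00 and one of 0.4 as 0.409. With a planted ratio of 1, 1 of 20 lists passed the threshold. With 30% of peaks placed on a second list the recovered value was 30.0%, and with 0% planted 0 of 10 lists passed. With no planted difference of medians 0 of 10 lists passed, and a difference of 40 was recovered as 38.8. A planted odds ratio of 9 was recovered as 8.83, and with 1 planted 0 of 10 lists passed. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.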

Results

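In this series, 4 histone modifications were profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the brain of female gray short-tailed opossum (Monodelphis domestica) fetuses at embryonic day 13. The gray short-tailed opossum is a laboratory marsupial, and in marsupials the paternal X chromosome is the one silenced in females. H3K4me3 and H3K9Ac are marks of active promoters, H3K27me3 is the mark laid down by Polycomb repressive complex 2, and H3K9me3 is a mark of constitutive heterochromatin. The 8 libraries comprised 2 per mark, each from a pool of 2 sister fetuses, and the pools came from different crosses. Both libraries of a mark refer to the same deposited peak list, so each mark has a single set of values, no replicate error can be given, and intervals describe only the variation along the genome within a list. The lists held 23987 H3K4me3 peaks, 17394 H3K27me3 peaks, 12157 H3K9Ac peaks and 979 H3K9me3 peaks. They covered 56.6 Mb, 34.5 Mb, 14.0 Mb and 1.11 Mb, with median widths of 2013 bp, 1316.5 bp, 1013 bp and 892 bp, in the same order. The lists hold no read counts, so the sequencing depth behind them is unknown. Positions are those of the deposited lists, whose genome build is not given in the sources used here, and no gene annotation matching them was used, so regions are named by position and not by gene.

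The series title names the X-inactivation status of the whole chromosome, and the first comparison set X against autosomes 1 to 8. H3K27me3 was concentrated on X. This chromosome made up 2.12% of the span covered by the lists but held 8194 of the H3K27me3 peaks, 47.1% of the list, against 7485 on all the autosomes together. The density was 107 peaks per Mb on X and 2.19 per Mb on the autosomes, a ratio of 49.0 (95% interval from resampled 1 Mb bins 42.5 to 55.4). No autosome exceeded 2.48 peaks per Mb, the value of chromosome 2. H3K27me3 peaks covered 16.8% of X and 0.546% of the autosomes, a ratio of 30.9 (25.6 to 36.3). With peaks less than 5 kb apart joined, the density ratio was 26.4 (24.2 to 28.3). X stood above every one of 10000 randomly placed autosomal windows of its own length for both measures, of which the densest held 6.09 peaks per Mb (two-sided window permutation test, adjusted p = 0.0008 for density and 0.0004 for cover, from the smallest p that the windows can give, 0.0002). These windows overlap one another and are not independent. The densest of 40 non-overlapping windows held 4.13 peaks per Mb (window permutation test, p = 0.0488, the smallest they can give, adjusted p = 0.0976).

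Of the active marks, H3K9Ac was sparser on X, and H3K4me3 passed the window test for neither density nor cover. H3K4me3 peaks numbered 6.55 per Mb on X and 6.46 per Mb on the autosomes, with a ratio of 1.01 (0.764 to 1.29) and an adjusted p of 0.679 in the window permutation test. They covered 1.29% of X and 1.53% of the autosomes, a ratio of 0.846 (0.622 to 1.101, window permutation test, adjusted p = 0.873). Among the top-scoring 50% of peaks the density ratio was 0.525 for H3K4me3 and 0.194 for H3K9Ac (adjusted p = 0.102 and 0.0004, window permutation test). H3K9Ac peaks were sparse on X, at 1.41 per Mb against 3.47 per Mb, a ratio of 0.408 (0.300 to 0.525, adjusted p = 0.0456 by the same permutation test). They covered 0.130% of X and 0.402% of the autosomes, a ratio of 0.324 (0.236 to 0.419). X lay below every one of the 10000 windows, though the lowest had 0.132% (window permutation test, adjusted p = 0.0004). H3K9me3 peaks were denser on X, at 0.878 per Mb against 0.205 per Mb, a ratio of 4.29 (2.98 to 5.79, window permutation test, adjusted p = 0.0340), from 67 peaks on X. Per Mb of sequence outside H3K27me3 peaks there were 0.252 H3K9me3 peaks on X (16 peaks) and 0.168 on the autosomes, a ratio of 1.50 (0.866 to 2.25). Per Mb of sequence inside H3K27me3 peaks there were 3.97 on X and 6.86 on the autosomes, a ratio of 0.578 (0.321 to 1.05). Both intervals include 1. Of the 128 autosomal H3K9me3 peaks inside H3K27me3, 31 and 11 lay in the chromosome 1 bins starting at 333 and 332 Mb. The H3K9me3 covered share was 3.97 times that of the autosomes and did not pass the permutation test (adjusted p = 0.0883). The H3K9Ac and H3K9me3 density calls were each lost under 3 of 6 other settings with 10000 windows, with adjusted p from the window permutation test between 0.0004 and 0.0709 for H3K9Ac and between 0.0299 and 0.0923 for H3K9me3. Both calls were also lost against 40 non-overlapping windows (window permutation test, adjusted p = 0.130 and 0.0976). The H3K9Ac call on covered share held under the 3 other settings run for it, under which the H3K9Ac density call held as well. The settings that ended the density call of H3K9Ac were not run for cover.

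**Figure D1:**
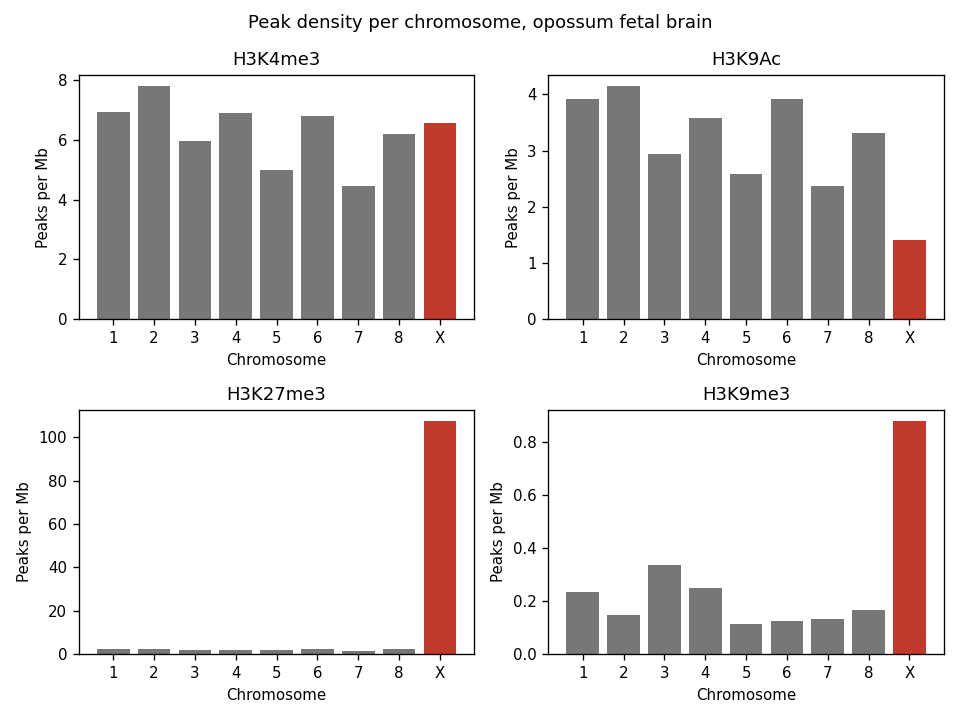
Peaks per Mb (vertical axis, from 0, on its own scale in each panel) on autosomes 1 to 8 (grey bars) and X (red bars) for each of the 4 deposited lists, 1 value per mark with no replicate error. H3K27me3 stood at 107 peaks per Mb on X and at most 2.48 on any autosome, and H3K9Ac at 1.41 on X against 3.47 over the autosomes.

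The strength of individual peaks was compared next, using the authors' peak score and the peak width. Peaks on X were weaker and narrower for 3 of the marks. The median H3K4me3 score was 154 on X and 344 on the autosomes, and the median width 1637.5 bp against 2029 bp (adjusted p = 2e-05 for both, two-sided permutation test, from 1e-05, the smallest p that 100000 resamples can give). The median H3K9Ac score was 64.2 against 84.5 (permutation test, adjusted p = 0.00423) and the median width 820.5 bp against 1017 bp (adjusted p = 0.00146). H3K27me3 peaks, although far more numerous on X, had a median score of 83.4 there and 120.4 on the autosomes, and a median width of 1185 bp against 1478 bp (permutation test, adjusted p = 2e-05 for both). H3K9me3 peaks had median scores of 57.8 and 58.1, which did not differ by the same permutation test (adjusted p = 0.873). The lowest score of this list is 50.03 and its median 58.9. Medians so close to the lowest score leave little room for a difference. Neighbouring peaks are not independent, and the calls for H3K4me3, H3K9Ac and H3K27me3 held with 1 median per 1 Mb bin.

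H3K27me3 peaks lay in runs on X and on the autosomes. When peaks less than 5 kb apart were joined, X held 261 H3K27me3 domains longer than 20 kb and the autosomes 196, and 72.7% of the X peaks belonged to domains of 3 or more peaks, against 34.5% on the autosomes. Peaks of the same number and widths placed at random gave 51.1% on X (at most 53.6% in 200 draws) and 0.0967% on the autosomes (at most 0.321%). The longest X domain, from 73275346 to 73466690, spanned 191 kb and held 47 peaks that filled 77.0% of it. The next ran from 72913563 to 73103876 (190 kb, 51 peaks), from 4440855 to 4570343 (129 kb, 42 peaks), from 70785675 to 70897932 (112 kb, 36 peaks) and from 71538686 to 71646749 (108 kb, 38 peaks). None of these 5 domains contained an H3K9Ac peak, and 2 of them contained H3K4me3 peaks (5 and 3). Cover varied along the chromosome. Among 77 bins of 1 Mb the median was 15.1% (interquartile range 7.36% to 23.0%), the lowest bin, starting at 25 Mb, had 1.14% and the highest, starting at 43 Mb, had 45.9%. All 77 bins exceeded the median autosomal bin (0.0916%), 63 exceeded the 99th percentile of 3417 autosomal bins (6.33%) and 15 exceeded the highest autosomal bin (27.3%). The last X bin, starting at 79 Mb with 44.1%, is among these 15. It is shorter than 1 Mb, since the last peak on X ends at 79333641. The median gap between neighbouring H3K27me3 peaks on X was 2.22 kb, and 55 gaps exceeded 100 kb. The longest, from 25291265 to 26181555, measured 890 kb and touched 1 H3K4me3 peak and no H3K9Ac peak. The next longest, from 39957816 to 40250308 (292 kb), contained 1 H3K4me3 peak and 1 H3K9Ac peak.

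Bins of X rich in H3K27me3 were also richer in active marks. Across the 77 bins, H3K27me3 cover correlated with the number of H3K4me3 peaks (Spearman rho 0.55, p = 0.0130, adjusted p = 0.0195, Pearson r 0.39, p = 0.0260, adjusted p = 0.0390) and with the number of H3K9Ac peaks (rho 0.47 and r 0.34, with the same p values), by a permutation test that rotates the bins along the chromosome and whose smallest unadjusted p is 0.0130. Leaving out the 2 bins farthest from the median cover gave r of 0.42 and 0.33. The short last bin at 79 Mb, with 4 H3K4me3 and 2 H3K9Ac peaks, was among the 77. For H3K9me3 the relation did not pass the permutation test (rho 0.25, p = 0.0649 before and after adjustment, r 0.25, p = 0.0779 before and after, r 0.20 without the 2 bins). These 3 relations are across bins of a single list per mark, and bins are not independent replicates.

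**Figure D2:**
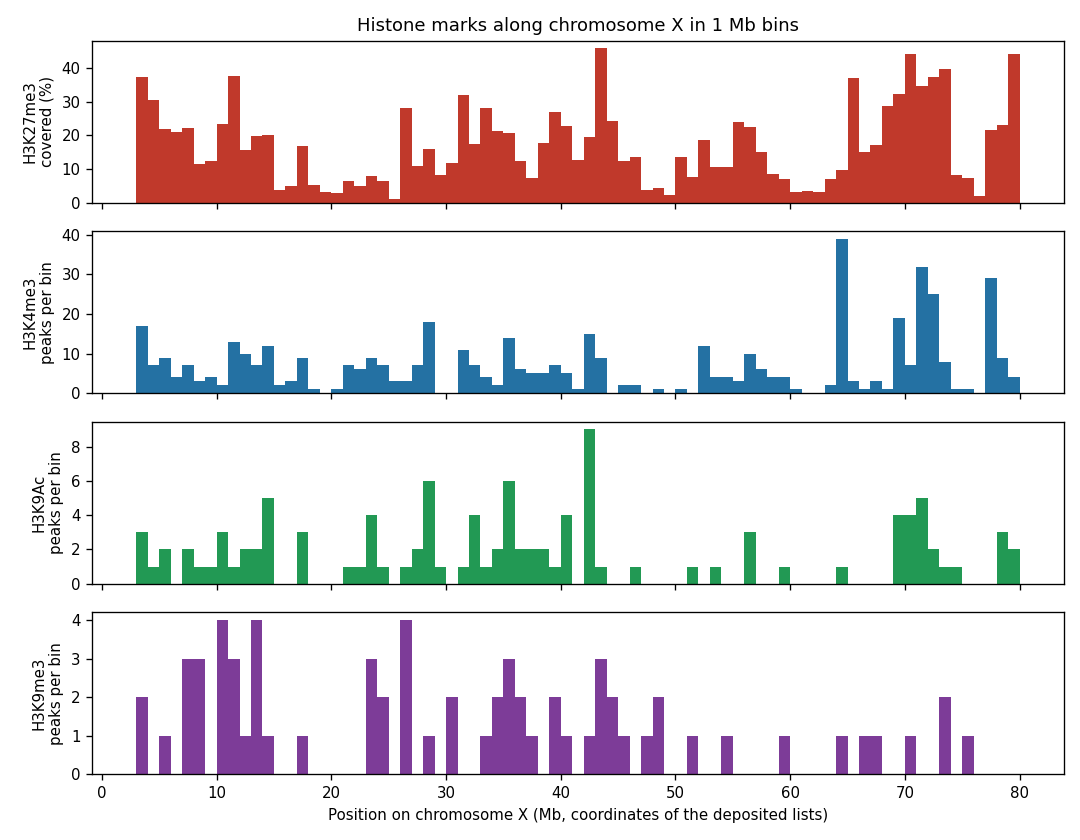
Chromosome X in bins of 1 Mb (horizontal axis, Mb in the coordinates of the deposited lists), with the percentage of bases under H3K27me3 peaks in the top row and the number of H3K4me3, H3K9Ac and H3K9me3 peaks per bin below, 1 value per bin. H3K27me3 cover ranged from 1.14% in the bin at 25 Mb to 45.9% in the bin at 43 Mb. The last bin, at 79 Mb, is shorter than 1 Mb.

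The marks were next compared for co-occupancy, as the share of peaks of one mark that shared at least 1 bp with a peak of another. On the autosomes H3K9Ac lay almost entirely within H3K4me3. Of 11858 autosomal H3K9Ac peaks, 90% (exact 95% interval 89.4% to 90.5%) overlapped H3K4me3, against 2.27% expected from 1000 circular shifts of the list along each chromosome. H3K27me3 and H3K4me3, the pair that marks bivalent promoters, also met on the autosomes. Of 7485 autosomal H3K27me3 peaks, 52.6% overlapped H3K4me3 (expected 2.99%, 17.6 times), and among the top-scoring 50% of both lists 27.8% did (12.2 times). Of the autosomal H3K9Ac peaks, 4.67% lay in H3K27me3 (expected 0.765%, 6.10 times, and 2.72 times among the top-scoring 50% of both lists). Of 699 autosomal H3K9me3 peaks, 18.3% lay in H3K27me3 (expected 0.731%), 15.5% in H3K4me3 (expected 2.19%) and 4.58% in H3K9Ac (expected 0.740%). Of the 128 autosomal H3K9me3 peaks in H3K27me3, 31 and 11 came from the chromosome 1 bins starting at 333 and 332 Mb. All 6 pairs exceeded the circular shifts, on X and on the autosomes alike (permutation by circular shift, adjusted p = 0.001998, the smallest that 1000 shifts can give). For the 4 X-linked H3K9me3 peaks in H3K9Ac the call ended without the peaks shared by all 4 marks, which left 1 peak (permutation, adjusted p = 0.306).

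On X the same marks met in different proportions. Only 4.65% of the 8194 X-linked H3K27me3 peaks overlapped H3K4me3, against 52.6% on the autosomes (odds ratio 0.0440, 95% interval 0.0392 to 0.0493, and 0.0348 to 0.0536 when 1 Mb bins were resampled). Against the circular shifts this was 2.13 times the expected share on X and 17.6 times on the autosomes. X held 500 H3K4me3 peaks against 8194 H3K27me3 peaks, so most X-linked H3K27me3 peaks had no H3K4me3 peak to meet. These list sizes cap the share, its odds ratio and the fold on X. A loss of co-occupancy on X is therefore not shown by them. Of 500 H3K4me3 peaks on X, 325 (65.0%) overlapped H3K27me3, against 16.5% of 22086 on the autosomes (odds ratio 9.39, 7.76 to 11.4, Fisher's exact test, adjusted p = 1.29e-124). When 1 Mb bins were resampled the interval was 6.36 to 14.1. No circular shifts were run in this direction. H3K27me3 covered 16.8% of X and 0.546% of the autosomes, so placement alone raises this share and its odds ratio on X. Of 108 H3K9Ac peaks on X, 58 (53.7%) overlapped H3K27me3, against 4.67% (odds ratio 23.6, 15.8 to 35.6, exact test, adjusted p = 4.85e-46). The exact tests count clustered peaks as independent, and resampled 1 Mb bins gave 14.1 to 37.2 here. H3K27me3 covered 16.8% of X, and circular shifts on X already placed 24.7% of H3K9Ac peaks in H3K27me3, so that the observed share was 2.18 times the expected one on X and 6.10 times on the autosomes. A share cannot exceed all peaks, so this high expected share caps the fold on X, and the 2 folds are not comparable. On the autosomes circular shifts placed only 0.765% there. Placement alone therefore raises the odds ratio, which does not show stronger co-occupancy on X. Acetylation was rarer at X-linked H3K4me3 peaks, of which 15% overlapped H3K9Ac against 42.4% on the autosomes (odds ratio 0.240, 0.185 to 0.308, and 0.172 to 0.326 when 1 Mb bins were resampled, exact test, adjusted p = 2.02e-38). X-linked H3K4me3 peaks have lower scores, and within 5 classes of score this odds ratio was 0.419 (0.318 to 0.551). Of 67 X-linked H3K9me3 peaks, 51 (76.1%) lay in H3K27me3 against 18.3% on the autosomes (odds ratio 14.1, 7.65 to 27.5, and 6.71 to 32.2 when 1 Mb bins were resampled, exact test, adjusted p = 1.26e-21). Against the circular shifts, which placed 25.1% and 0.731% there, these shares were 3.03 times the expected value on X and 25.1 times on the autosomes, the reverse order of the odds ratio. The expected share of 25.1% caps the fold on X in the same way, so these folds do not show weaker co-occupancy on X. Placement alone also raises the odds ratio, which does not show stronger co-occupancy on X. The share of H3K9me3 peaks in H3K4me3 (22.4% on X and 15.5% on the autosomes) did not pass Fisher's exact test (adjusted p = 0.176, odds ratio 1.58, 0.795 to 2.97), nor did the share in H3K9Ac (5.97% and 4.58%, adjusted p = 0.546, odds ratio 1.32, 0.329 to 3.91). When 50% of the shorter peak had to be shared, the difference for H3K4me3 passed (odds ratio 1.90, exact test, adjusted p = 0.0471). All 12 ordered pairs were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment, and the remaining 5 passed, of which H3K9Ac in H3K9me3 (odds ratio 13.4) did not without the peaks shared by all 4 marks (4.37, adjusted p = 0.255). Among the top-scoring 50% of peaks the odds ratio was 5.12 for H3K9me3 in H3K27me3, 35.6 for H3K9Ac in H3K27me3 and 0.0684 for H3K27me3 in H3K4me3, the last again capped by the list sizes on X. For the first 2, circular shifts placed 15.4% and 15.1% there on X, against 0.629% and 0.632% on the autosomes. Placement therefore raises these 2 odds ratios as well.

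**Figure D3:**
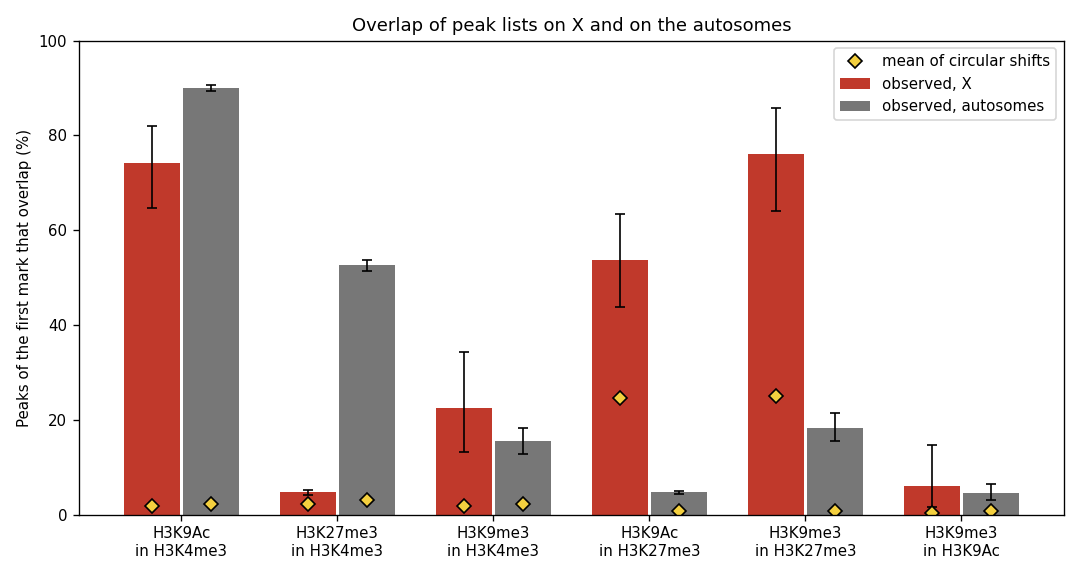
Percentage of peaks of the first mark that share at least 1 bp with a peak of the second (vertical axis), on X (red) and on the autosomes (grey). Bars are the observed shares with exact 95% binomial intervals, and diamonds the mean of 1000 circular shifts. H3K27me3 peaks met H3K4me3 in 52.6% of cases on the autosomes and 4.65% on X, whereas H3K9Ac and H3K9me3 peaks on X met H3K27me3 in 53.7% and 76.1% of cases. Circular shifts placed 24.7% and 25.1% of these peaks there. X held 500 H3K4me3 peaks against 8194 H3K27me3 peaks, which caps the share of 4.65%.

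H3K4me3 peaks were then divided by the other marks they carried. On the autosomes 8713 peaks (39.5%) carried H3K9Ac without H3K27me3, 3003 (13.6%) carried H3K27me3 without H3K9Ac, 644 (2.92%) carried both and 9726 (44.0%) neither. On X these classes held 31 (6.20%), 281 (56.2%), 44 (8.80%) and 144 peaks (28.8%). On the autosomes H3K27me3 was rarer where H3K9Ac was present, at 6.88% of H3K4me3 peaks with H3K9Ac and 23.6% of those without it (odds ratio 0.239, 0.218 to 0.262, Fisher's exact test, p = 1.56e-261). On X the shares were 58.7% and 66.1% (odds ratio 0.728, 0.429 to 1.25), and the difference did not pass Fisher's exact test (p = 0.238). The 2 odds ratios differed by a factor of 3.04 (95% interval 1.42 to 5.88 from 10000 resamples of 1 Mb bins). This contrast was not adjusted for peak width or for overlap by placement alone. On X, H3K4me3 peaks with H3K9Ac had median widths of 2597.5 bp (with H3K27me3) and 2018 bp (without), against 1661 bp and 1321 bp for those without H3K9Ac. Wider peaks meet H3K27me3 more often by placement where its cover is high, and it was 16.8% on X against 0.546% on the autosomes. The 44 X-linked peaks with both marks had a median H3K4me3 score of 531 and the 31 with H3K9Ac alone a median of 300.3. On the autosomes the order was the other way, with 658 for both marks and 809 for H3K9Ac alone. These differences of score were not tested.

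The cover of H3K27me3 around H3K4me3 peaks separated the chromosomes further. Around autosomal H3K4me3 peaks without H3K9Ac, H3K27me3 covered 18.8% of the bases inside the peak (95% interval 17.6 to 20.05), 13.5% within 1 kb and 1.78% at 20 to 50 kb. Around autosomal peaks with H3K9Ac it covered 4.11%, 2.42% and 0.786%. On X, cover inside peaks without H3K9Ac was 45.9% (39.4 to 53.9) and inside peaks with H3K9Ac 39.3% (28.0 to 49.8). At 20 to 50 kb it was 22.3% (18.2 to 26.1) and 20.9% (16.9 to 24.96). The cover of the whole chromosome was 16.8%, below the intervals inside the peaks and at 20 to 50 kb, and within the intervals for peaks with H3K9Ac at 2 to 5 kb (14.8 to 26.4), 5 to 10 kb (15.8 to 26.9) and 10 to 20 kb (15.2 to 25.1).

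**Figure D4:**
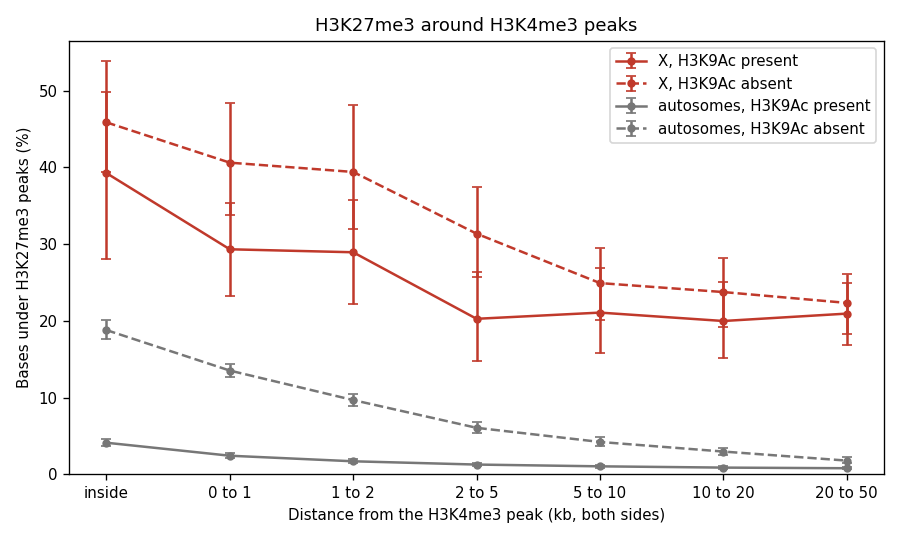
Percentage of bases under H3K27me3 peaks (vertical axis, from 0) inside H3K4me3 peaks and in 6 distance classes on both sides of them (horizontal axis, kb), for peaks with H3K9Ac (solid) and without (dashed), on X (red) and the autosomes (grey). Error bars are 95% intervals from resampled 1 Mb bins. Cover inside the peaks was 45.9% and 39.3% on X against 18.8% and 4.11% on the autosomes.

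On X the H3K4me3 peak with the highest score lay at 14464382 to 14471523 (7142 bp, score 2054), followed by 43227289 to 43231852 (score 1923), 40252527 to 40257749 (score 1625), 69898684 to 69903576 (score 1464) and 56144857 to 56152459 (score 1446). The first 3 overlapped H3K9Ac and not H3K27me3, the fourth overlapped neither mark, and the fifth overlapped both. The 5 highest-scoring autosomal H3K4me3 peaks all overlapped H3K9Ac and not H3K27me3. They included 269074150 to 269082425 on chromosome 3 and 233135829 to 233141296 on chromosome 2, each with a score of 3233. The highest-scoring H3K9Ac peaks of the autosomes, at 211982618 to 211989156 on chromosome 3 (score 1185) and 156340246 to 156346354 on chromosome 8 (score 1155), also lay in H3K4me3 and outside H3K27me3. The highest-scoring H3K9Ac peak on X, at 39117738 to 39118560, reached 283 and overlapped all 3 other marks. Its borders lay close to those of the highest-scoring H3K9me3 peak on X (39117709 to 39118584). Sequence that collects reads in every library was not excluded at this place. The H3K9Ac peak with the second score on X, at 71013632 to 71015847 (score 222), overlapped H3K4me3 and H3K27me3.

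Among H3K27me3 peaks the 5 highest-scoring on the autosomes all overlapped H3K4me3 and none overlapped H3K9Ac. They included 95949355 to 95960092 on chromosome 5 (score 3220) and 92799688 to 92813259 on chromosome 1 (score 3198). Scores at this end have a ceiling, with 132 H3K27me3 peaks at exactly 3100 and 7 above it, so the order at the top is not an order of strength. The longest autosomal H3K27me3 domain ran from 332954375 to 333265345 on chromosome 1 (311 kb, 35 peaks) and contained 11 H3K4me3 peaks, 32 H3K9me3 peaks and no H3K9Ac peak. The others of the 5 longest lay on chromosome 8 from 297273075 to 297435740 (163 kb), chromosome 2 from 201099206 to 201246008 (147 kb), chromosome 4 from 187408699 to 187543137 (134 kb) and chromosome 1 from 332591442 to 332715021 (124 kb). Those on chromosomes 8, 2 and 4 contained 11, 16 and 15 H3K4me3 peaks and 6, 1 and 3 H3K9Ac peaks. The domain on chromosome 1 from 332591442 contained 1 H3K4me3 peak, 11 H3K9me3 peaks and no H3K9Ac peak. On X the highest-scoring H3K27me3 peaks, at 11956534 to 11959795 and at 26600767 to 26602232, both reached 3100 and both overlapped H3K4me3 and H3K9me3. The latter lies close to the borders of its H3K9me3 peak (26600971 to 26602211), and sequence that collects reads in every library was not excluded there. The others of the 5 differed. The peak at 13767395 to 13781882 (score 2784) overlapped H3K9me3 and not H3K4me3. The peak at 73288222 to 73309673 (score 2320) overlapped neither, and that at 6594092 to 6609320 (score 2118) overlapped H3K4me3 and not H3K9me3.

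H3K4me3 itself formed few long domains. The longest on X, from 77208177 to 77267332 (59.2 kb, 13 peaks), contained 7 H3K27me3 peaks and no H3K9Ac peak, and the next, from 64857751 to 64878729 (21.0 kb, 7 peaks), contained neither mark. On the autosomes the longest ran from 203919149 to 204022736 on chromosome 3 (104 kb, 9 peaks), with 8 H3K27me3 peaks and no H3K9Ac peak. By contrast, the domain from 251849004 to 251897105 on chromosome 8 (48.1 kb) held 10 H3K9Ac peaks and no H3K27me3 peak. H3K9Ac domains on X reached at most 6.13 kb (17488770 to 17494897), against 29.2 kb on the autosomes (chromosome 8, 251853194 to 251882397). The longest H3K9me3 domain, from 333191576 to 333250827 on chromosome 1 (59.3 kb, 21 peaks), lay inside the longest H3K27me3 domain. On X the longest H3K9me3 domain, from 26479978 to 26484156, measured 4.18 kb. The highest-scoring H3K9me3 peaks on X, at 39117709 to 39118584 (score 2536) and 8225711 to 8227226 (score 1410), overlapped peaks of all 3 other marks, and the highest-scoring autosomal one, at 15707196 to 15709722 on chromosome 7 (score 666), overlapped H3K4me3 and H3K27me3. The peak at 39117709 has nearly the borders of the highest-scoring H3K9Ac peak on X, where sequence that collects reads in every library was not excluded.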

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

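The tests in this part were chosen after the result was seen, except the comparison of H3K27me3 scores of X peaks with and without H3K9me3, whose division by width was added later.

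Sequence not placed on a chromosome took no part in the main comparisons, and all 4 marks had peaks in it, with 1401 for H3K4me3, 191 for H3K9Ac, 1715 for H3K27me3 and 213 for H3K9me3. Over 103 Mb this is 16.6 H3K27me3 peaks per Mb, against 2.19 on the autosomes and 107 on X. H3K4me3 stood at 13.6 per Mb (6.46 on the autosomes and 6.55 on X) and H3K9me3 at 2.07 per Mb (0.205 and 0.878). H3K9Ac stood at 1.85 per Mb (3.47 and 1.41). In 6 of the 104 unplaced bins of 1 Mb, those starting at 5, 6, 22, 23, 27 and 28 Mb, H3K27me3 was denser than in any autosomal bin (59 peaks), with 61 to 126 peaks and 32.9% of all unplaced H3K27me3 peaks, against a median of 99 in X bins. Collapsed repeats that gather reads in every library would raise H3K4me3 as well, which was 1.68 times as dense there as in the other unplaced bins (95% interval 0.891 to 2.75), against 1.49 times for H3K9Ac, 0.805 times for H3K9me3 and 8.02 times for H3K27me3, but the choice of bins by H3K27me3 raises that fold, and this explanation stays open too. These stretches may belong to X, which stays open: 9.20% of their H3K27me3 peaks overlapped H3K4me3 (exact 95% interval 6.95% to 11.9%), against 4.65% on X, 24.5% in the other unplaced bins, 30.4% (24.8% to 36.5%) in the 6 densest autosomal bins and 52.6% on all autosomes, but bins chosen for many H3K27me3 peaks have a lower share by that choice, and the interval leaves out the X value.

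The excess of H3K27me3 on X was weighed against 2 technical explanations. More reads from X in every library would raise H3K4me3 as well, whose density ratio was 1.01 (0.764 to 1.29), and H3K9Ac, which was lower on X. The division of broad domains into many short peaks accounts for part of the ratio at most, since domains joined over gaps of less than 5 kb still gave a ratio of 26.4 (24.2 to 28.3). Whether the excess reflects the inactive X of these females cannot be told apart from a property of the opossum X in both sexes, because 0 male lists were at hand, and a difference in background that a control library would remove was not tested.

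H3K9me3 peaks lay in peaks of other marks above the circular shifts, and without the places shared by all 4 marks they still did (permutation, adjusted p at most 0.00240), in H3K27me3 22.8 times the expected share on the autosomes (25.1 before) and 3.01 on X (3.03 before), and in H3K4me3 6.41 (7.05 before) and 10.5 times (12.5 before), with only the H3K9Ac pair on X lost. Sequence that gathers reads in every library stays open, since such places can miss the threshold of a list and the test of peak borders at the 41 places shared by H3K9me3 and H3K9Ac depended on the matching: shared over joint length was 0.538 (95% interval 0.437 to 0.613) against 0.389 for all places shared by H3K4me3 and H3K9Ac, whose widths differ, and differed by -0.0884 (-0.228 to -0.0192) from those of the nearest widths. Binding of the H3K9me3 antibody to H3K27me3 stays open on X and on the autosomes, since H3K27me3 peaks with H3K9me3 had a median H3K27me3 score 120.6 above the others on X (48 peaks) and 136.9 above on the autosomes (94 peaks), more than the 41.5 and 71.0 given by permutation within 10 classes of width (p = 0.0002, the smallest it can give, and p = 0.0102). Of the 10% of H3K27me3 peaks with the highest scores, not matched for width, 2.44% on X and 4.27% on the autosomes carried H3K9me3, against 0.586% and 1.26% of all. The doubt bears on the H3K9me3 excess on X, since the ratio was 1.50 (0.866 to 2.25) per Mb of sequence outside H3K27me3 peaks and 0.578 (0.321 to 1.05) inside them, neither apart from 1, and a true joint presence of both marks, which predicts the same, was not tested.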

How the results depend on the processing

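Lengths counted from position 0, the removal of peaks shared by all 4 marks and the classes of score were chosen after the results were seen. Of 180 results recomputed under another setting, 158 kept their direction and their side of the threshold, 14 lost the call (6 of them under the 2 settings with few reference values named next), 1 gained it and 7 changed direction, and no result that had passed its test changed direction. The H3K27me3 density ratio stayed between 26.4 (joined peaks) and 52.5 (without chromosomes 1 and 2). It lost its call only where few reference values were left, as the ratio of 49.0 against 40 non-overlapping windows (permutation of the window, p = 0.0488, the smallest they can give, adjusted p = 0.0976) and against 8 autosomes ranked whole (exact rank test, p = 0.222, the smallest that this rank can give, so it tests nothing). Under those 2 settings the H3K9Ac ratio of 0.408 (adjusted permutation and exact rank p = 0.130 and 0.296) and the H3K9me3 ratio of 4.29 (adjusted p = 0.0976 and 0.296) also lost theirs. The H3K9Ac density call further ended without chromosomes 1 and 2 (ratio 0.450), with unplaced sequence counted as autosomal (0.413) and with joined peaks (0.440), and the H3K9me3 call without chromosomes 1 and 2 (4.21), with unplaced sequence as autosomal (3.39) and in the top-scoring 50% of peaks (4.10), where fewer peaks are left. The cause of the other losses was not tested. The H3K4me3 density ratio of 1.01, which did not pass, was below 1 in the top-scoring 50% (0.525), with unplaced sequence as autosomal (0.982), with joined peaks (0.952) and with lengths from position 0 (0.976). H3K9me3 values rest on few peaks. Without the peaks shared by all 4 marks, the enrichment of X-linked H3K9me3 in H3K9Ac was 6.10 in place of 24.4 (circular-shift permutation, adjusted p = 0.306), the odds ratio of H3K9Ac in H3K9me3 was 4.37 in place of 13.4 (exact test, adjusted p = 0.255), and that of H3K9me3 in H3K9Ac turned to 0.441, each with 1 peak left on X. The odds ratio of H3K9me3 in H3K4me3 reached 1.90 (exact test, adjusted p = 0.0471) when 50% of the shorter peak had to be shared. The H3K9me3 score and width differences, neither past the test, turned to 1.42 and 34 bp with medians of 1 Mb bins. Other settings for promoters and gene lists (other windows, other gene sets, CpG classes, windows of consecutive genes) and bases other than N as length were not run, for want of an annotation or sequence in the coordinates of the lists. Depth limits cannot be given without read counts, and weak peaks below the authors' threshold are not in the lists. No paired analysis was possible because both libraries of a mark share a single peak list, and leaving out a replicate could not be run for the same reason.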

Other observations

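All patterns and tests in this part were chosen after the data were seen.

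Autosomal H3K9me3 peaks lay in 458 bins of 1 Mb, with 7.58% of peaks in domains of 3 or more, and some places were denser. No random placement was run for this mark. The last 27.9 Mb of chromosome 3, from 500 Mb on, held 87 of its 178 H3K9me3 peaks (48.9%), a density of 3.12 per Mb against 0.182 per Mb on the rest of the chromosome. The bin starting at 501 Mb held 20 of them. Of the 87 peaks, 6 lay in H3K27me3 and 11 in H3K4me3, so most carried H3K9me3 without those marks. The bins starting at 332 and 333 Mb of chromosome 1 held 12 and 31 H3K9me3 peaks, of which 11 and 31 lay in H3K27me3, and the bin at 404 Mb of chromosome 4 held 11, none of them in H3K27me3 (0 peaks). Across the whole H3K9me3 list, unplaced peaks included, the weakest peaks stood apart from other marks. Of the lower 50% by score 74.6% overlapped none, against 21.4% of the top 10%. Both H3K4me3 and H3K27me3 were overlapped by 6.34% of the lower 50% and 60.2% of the top 10%. Peaks were not matched for width.

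On X, 31 H3K4me3 peaks carried H3K9Ac and no H3K27me3 peak, the combination most common at acetylated H3K4me3 peaks on the autosomes. By H3K4me3 score they were led by 14464382 to 14471523 (score 2054), 43227289 to 43231852 (score 1923), 40252527 to 40257749 (score 1625), 35481126 to 35486234 (score 1372), 40180751 to 40183865 (score 1081) and 32931948 to 32934496 (score 985). The peak at 40180751 lies inside the 292 kb gap in H3K27me3 from 39957816 to 40250308, and the one at 40252527 starts just past its end. Allele-specific data were not used here. The remaining 44 acetylated H3K4me3 peaks on X also overlapped H3K27me3, and a list that pools both X chromosomes does not show whether the marks share a chromosome.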
